A study of Mus musculus with 2 samples.

How the data were processed

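H3K36me3 ChIP-seq was done on pooled mouse embryonic facial prominences of embryonic day 12.5, in 2 biological replicates with 2 technical replicates each. The deposited descriptions of the files say that each replicate's peak list was made from its 2 technical replicates together and its own control, that a further list was made from both replicates pooled, and that the replicated list was derived from the pooled list and the replicates' lists. All 109603 replicated peaks were found to be identical to pooled peaks, 57.7% of that list. The aligner, peak caller, thresholds and read numbers are not given in the sources used here. Per the labels, the genome build is mm10, and no peak ran past the end of a chromosome of the GRCm38 reference sequence.

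Each peak's enrichment is a ratio that the authors deposited for that peak over its background, and it was used only to describe and rank peaks within a list. The −log10 p and −log10 q of each peak are also as the authors deposited them. The smallest −log10 p was 2.01 in replicate 1, 2.03 in replicate 2 and 2.02 in the replicated list, and 99.3% of the replicated peaks had a −log10 q of at least 2. The narrowest peaks were 155 bp in replicate 1, 200 bp in replicate 2 and 180 bp in the replicated list, with median widths of 282, 379 and 624 bp. Replicates were thus compared by peak positions and covered length, not by peak heights. Because the depth is unknown, no interval for counting error can be given, and the spread given is the SD between the 2 replicates.

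Gene bodies and exons came from GENCODE release M21 on GRCm38. Protein-coding genes of chromosomes 1 to 19 and X were used, with the longest taken where a symbol occurred more than once (27 genes left out), giving 21728 genes. Peaks on chromosome Y and on unplaced or unlocalized sequence entered no comparison. The covered share of a gene is the percent of its annotated body, introns included, that lies under peaks, and a gene was called marked at 20% or more of the body under replicated peaks. As peaks carry no strand, a peak counts for every gene it overlaps, and 4707 genes overlap another protein-coding gene. Replicate lists were compared by overlaps of at least 1 bp, by a Jaccard index and by 100 shuffles within chromosomes.

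Tests over chromosomes flipped the signs of the 20 chromosome values 100000 times (two-sided). They were used for the share of peak length in gene bodies, for the 3' against the 5' part of marked genes of at least 5 kb, and for internal exons of the longest transcript against stretches 300 to 800 bp away on both sides that hold no annotated exon. For each of 28 gene lists and 8 families the number of marked members was compared with 10000 random lists drawn from the other genes in the same 10 bins of gene length, two-sided, with Benjamini-Hochberg adjustment over all 36. The smallest p these draws can give is 0.0002, or 0.0008 after adjustment. All 508 listed genes were matched by symbol. Ribosomal protein genes were taken without the kinases and other genes that only share the prefix of their symbols. Genes in a list were treated as independent draws, which neighbours in a cluster are not.

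The groups, tests, thresholds, lists, alternatives and the rule for naming genes were chosen before the data were examined. Exceptions were the tests of gene length and gene content on chromosome X and of Zfp genes with a neighbour. The rule named, per list, up to 3 members with the largest covered share and up to 2 with the smallest, the 10 genes with the largest share and the 10 with the most covered length, the 5 largest differences between replicates each way, the 5 longest domains and the 5 peaks of highest enrichment. Setd2, Dlx2, Dlx5, Dlx6, Twist1, Msx1, Pbx1, Six1 and, on chromosome X, all genes but Hprt, Rpl10 and Alas2 were named in addition, after their values were seen. The alternatives were the pooled list, each replicate's own list, peaks with −log10 q of at least 2 or −log10 p of at least 5, thresholds of 10% and 40%, genes that overlap no other, genes of at least 5 kb, Fisher's exact test without matching, medians in place of counts, stricter overlaps, and shuffles outside assembly gaps, which make up 2.82% of the chromosomes.

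The work was done in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Covered lengths were checked against bedtools 2.31.1 and were equal for all 21728 genes. Tested on simulated data, 2.40% of 500 random lists of 20 genes had a p under 0.05 and 100% of lists with 70% marked members did. Of 2000 sets of 20 random chromosome values 6.25% had a p under 0.05, and of sets shifted by 1 SD 98.8% did.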

Results

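Trimethylation of histone H3 at lysine 36 (H3K36me3) is laid down over the bodies of genes by SETD2, which travels with elongating RNA polymerase II. It was mapped here by chromatin immunoprecipitation and sequencing (ChIP-seq) in the mouse facial prominences, the embryonic swellings that form the jaws, nose and palate, at embryonic day 12.5. There was 1 group of 2 biological replicates, each a pool of embryos of both sexes: 120 embryos in replicate 1 and 88 in replicate 2. The data are 4 lists of enriched regions (peaks) on the mm10 build: 197898 peaks called in replicate 1, 159603 in replicate 2, 190102 in both replicates pooled, and 109603 replicated peaks, which were the main list used here. Peaks on chromosomes 1 to 19 and X spanned 82.1 Mb in replicate 1, 92.3 Mb in replicate 2 and 104 Mb in the replicated list, 3.94% of these chromosomes. Each peak carries the authors' enrichment value, which in the replicated list ran from 1.28 to 14.97 with a median of 3.25. The number of reads behind the peaks is not given in the sources used here, so the depth is unknown. With no second tissue or stage in the series, the comparisons are between replicates, parts of genes, groups of genes and chromosomes.

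The first question was whether the 2 replicates marked the same genes. Mcm2, a subunit of the replicative helicase, had 78.4% of its body under peaks in replicate 1 and 81.7% in replicate 2 (80.1% ± 2.37, SD, n = 2). The splicing factor gene Sf3a1 had 83.2% and 81.7%, and Prr12 had 86.5% and 86.4%. The genes of at least 5 kb that differed most included Nme2, a nucleoside diphosphate kinase gene, with 25.7% in replicate 1 and 54.5% in replicate 2, Tmem167b with 17.1% and 45.7%, and Fadd, the adaptor of death receptors, with 18.4% and 45.5%. In the other direction stood Clba1 with 30.2% and 5.37%, Neil1, a DNA glycosylase gene, with 27.7% and 3.63%, and Paxx, a DNA end-joining factor gene, with 20.3% and 0%.

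Across 21728 protein-coding genes, the covered shares of the replicates correlated with Pearson's r = 0.977 and Spearman's rho = 0.957, a correlation across genes, which are not independent replicates. Of these genes, 5395 had at least 20% of the body covered in both replicates, 184 in replicate 1 alone and 628 in replicate 2 alone. Below, a gene is called marked when replicated peaks cover at least 20% of its body, or, for values of a replicate, when that replicate's own peaks do. Peaks of replicate 1 were overlapped by 1 bp or more of a replicate 2 peak in 69.6% of cases, against 5.77% ± 0.0618 (SD over 100 shuffles) after random placement within chromosomes. For the peaks of replicate 2 the share was 71.5%, against 6.28% ± 0.0671. The covered lengths overlapped with a Jaccard index of 47.6%, against 1.88% ± 0.0248 for shuffled peaks. With the replicate 1 peaks put in 10 equal bins by −log10 p, 98.0% of the highest bin were overlapped by replicate 2 and 46.8% of the lowest. The shares fell when a larger overlap was asked for: with a reciprocal overlap of 50%, 28.9% of the replicate 1 peaks and 35.8% of the replicate 2 peaks were shared.

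**Figure D1:**
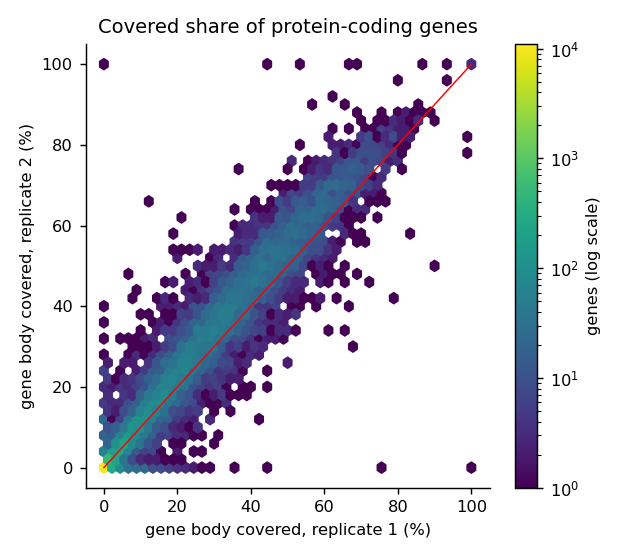
Share of each protein-coding gene body covered by peaks (%) in replicate 1 (x axis) and replicate 2 (y axis), with hexagons coloured by the number of genes on a log scale and the line of equality in red. Pearson's r was 0.977 across 21728 genes, and of the 6457 genes marked in the replicated list 5157 had the larger share in replicate 2.

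The second question was where in the genome, and where within genes, the mark lay. The longest continuous domain, with replicated peaks joined over gaps of up to 1 kb, was 101705 bp long on chromosome 4 (139389892 to 139491596) and ran over Ubr4, which encodes a large E3 ubiquitin ligase. The next were 97525 bp over the chromatin remodeller gene Chd2 on chromosome 7 (73425346 to 73522870), 93345 bp over the autophagy scaffold gene Wdfy3 on chromosome 5 (101839939 to 101933283), 90871 bp over Trrap, a scaffold of histone acetyltransferase complexes, on chromosome 5 (144770720 to 144861590), and 77318 bp over Smarca4, the BRG1 ATPase gene, on chromosome 9 (21632819 to 21710136). Exons made up 17.3% of the Ubr4 domain and 8.06% of the Smarca4 domain, the rest being mostly intron. There were 38908 domains, of which 3065 were at least 10 kb long and held 43.0% of the domain length.

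Of the replicated peak length, 94.8% lay in bodies of protein-coding genes, against 41.0% after shuffling, and the share was higher on 20 of 20 chromosomes (two-sided sign-flip permutation p = 2e-05). Exons of protein-coding genes held 24.2% of the peak length and introns 70.6%, while exons make up 3.64% of these chromosomes and introns 35.7%. Positions within 1 kb of a protein-coding transcription start held 0.416% of the peak length but 1.56% of the genome. In marked genes of at least 5 kb (5809 genes), cut into 3 equal parts, peaks covered 66.3% of the 3' part and 23.4% of the 5' part, a difference of 43.0 percentage points in the same direction on 20 of 20 chromosomes (sign-flip permutation p = 1e-05, the smallest that 100000 flips can give). With the body in 10 equal parts, cover rose from 5.59% in part 1 to 69.0% in part 9 and was 63.5% in part 10. Internal exons of marked genes were covered over 70.2% of their length and the intron stretches 300 to 800 bp away over 56.2%, a difference of 14.0 percentage points, positive on 20 of 20 chromosomes (sign-flip permutation p = 1e-05, 18623 exons). In the replicates' own lists this exon difference was 14.9 and 14.0 percentage points, and the 3' difference 36.2 and 39.1.

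**Figure D2:**
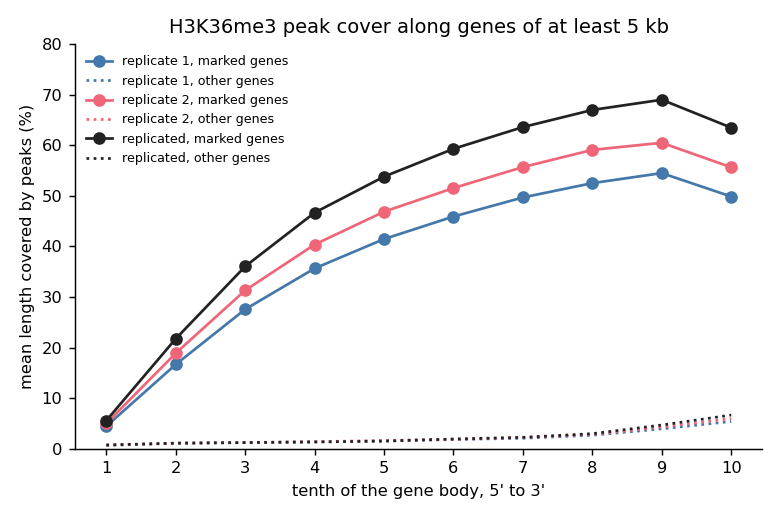
Mean share of length covered by peaks (%, y axis) in each of 10 equal parts of the gene body from 5' to 3' (x axis), for the peak lists of replicate 1, replicate 2 and the replicated peaks, in 5809 genes marked in the replicated list (solid lines with points) and the other genes of at least 5 kb (dotted lines). In marked genes the replicated peaks cover 5.59% of part 1 and 69.0% of part 9.

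The third question was which genes carried the mark. The genes of at least 5 kb with the largest covered shares were Gigyf1, a translational repressor gene, with 97.5% (87.6% ± 2.38 in the replicates' own lists, SD, n = 2), the Integrator subunit gene Ints1 with 93.6% (86.0% ± 0.696), Pla2g4b with 93.3%, Trrap with 93.0% (84.6% ± 4.39), Sf3a1 with 91.7%, the RNA exosome nuclease gene Exosc10 with 90.6%, Prr12 with 90.5%, Rnf40, a ubiquitin ligase gene for histone H2B, with 90.2%, Kdm4a, a demethylase of H3K36, with 90.2%, and Phykpl with 90.0%. Of these, Gigyf1, Pla2g4b and Phykpl overlap another annotated protein-coding gene. By covered length, Wdfy3 had 123103 bp under peaks, Ubr4 116967 bp, the fibrillin gene Fbn2 116870 bp, Eif4g3 113435 bp and the nuclear envelope gene Syne2 112610 bp. Macf1 (102986 bp), Clasp1 (94922 bp) and Trio (93397 bp), which act on the cytoskeleton, followed. The largest sums, 571969 bp at Gm20388 on chromosome 8 and 217288 bp at Fgfr2 on chromosome 7, came from annotated bodies of 4434882 and 2960900 bp that span many other genes.

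In all, 6457 of the 21728 protein-coding genes (29.7%) were marked in the replicated list, and 11390 (52.4%) had no base under a peak. The count was 5579 in the list of replicate 1 and 6023 in that of replicate 2. Of the 6457 genes, 5394 were also marked in both replicates' own lists, and some, such as Fgfr3, were marked in neither. The marked share rose from 9.34% in the shortest of 10 bins of gene length to 43.6% among genes of 25102 to 36746 bp and was 7.82% in the longest bin, so gene lists were compared with 10000 random lists of matched gene length. Of the 36 lists and families fixed before the data were examined, 9 were marked more often than random lists, 21 less often and 6 not past the threshold of an adjusted p of 0.05.

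Of the lists and families tested, the cell cycle, H3K36 methylation, ribosomal protein and ubiquitous genes had the largest shares of marked members. This did not hold for all genes that dividing cells use, since none of the 67 replication-dependent histone genes was marked. All 22 cell cycle genes were marked, against 37.3% expected (adjusted permutation p = 0.0008), led by the helicase subunit genes Mcm2 (88.9% of the body covered), Mcm5 (85.5%) and Mcm3 (83.2%), with the lowest values at the DNA polymerase clamp gene Pcna (37.6%) and the spindle checkpoint gene Bub1 (38.4%). Among the writers, readers and erasers of H3K36 methylation, 14 of 16 were marked, against 30.5% expected (adjusted permutation p = 0.0008). They included Kdm4a, the acetyltransferase scaffold gene Brpf1 (79.4%), the elongation factor gene Supt6 (76.6%, overlapping Sdf2) and Setd2 itself (49.5%), while Kdm2b (12.03%) and the DNA methyltransferase gene Dnmt3b (12.2%) were under the threshold. The ubiquitous list had 16 of 20 members marked, against 33.5% expected (adjusted permutation p = 0.0008), from the translation factor gene Eef2 (82.3%), the chaperone gene Hsp90ab1 (76.4%) and the nucleolin gene Ncl (69.6%) down to Eef1a1 (5.15%) and Hprt (1.48%). Ribosomal protein genes were marked in 60 of 73 cases, 82.2% against 19.3% expected (adjusted permutation p = 0.0008). Rps15a (82.9%), Rps28 (82.2%, a gene that overlaps Kank3) and Rps5 (81.6%) stood highest, and Rpl10 and Rpl36 had no base under a replicated peak. Rpl10 did have 12.8% under peaks of replicate 1, but 0% in replicate 2.

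Genes of the facial mesenchyme, the connective tissue precursor that fills the prominences, fell on both sides. The mesenchymal matrix and adhesion list had 14 of 20 members marked, 70% against 27.7% expected (adjusted permutation p = 0.00144, 67.5% ± 3.54 in the replicates' own lists, SD, n = 2). The fibronectin gene Fn1 was covered over 86.3% of its body (70.2% in replicate 1 and 82.9% in replicate 2), the collagen genes Col1a1 over 74.7% and Col6a1 over 73.9%, while Thy1 had 0% and the decorin gene Dcn 0.797%. The facial mesenchyme transcription factors were marked in 3 of 40 cases, 7.5% against 27.7% expected (adjusted permutation p = 0.00775). These were Alx4 (27.5% covered), which is required for the cranial skeleton and whose annotated body overlaps Ext2, Sox11 (22.4%) and the limb and craniofacial homeobox gene Prrx1 (21.4%). In the replicates' own lists none of the 40 was marked in replicate 1 and 2.50% in replicate 2. Replicated peaks covered 0% of Twist1, Dlx1, Dlx2, Dlx5, Dlx6 and Barx1, and 9.22% of Msx1. Dlx2 did have 16.6% of its body under peaks of replicate 1, and Barx1 6.27%, but both had 0% in replicate 2.

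Of the signalling pathways that pattern the face, each was set against random lists and none against another. Of 14 hedgehog pathway genes 9 were marked, 64.3% against 28.3% expected (adjusted permutation p = 0.0136), among them Kif7 (61.1%), Gli1 (50.7%, with 21.8% in replicate 1 and 38.4% in replicate 2) and the receptor gene Ptch1 (46.7%, 41.7% ± 5.44 in the replicates' own lists). Kif7 overlaps Ticrr and Gli1 overlaps Arhgap9. The ligand gene Shh and the antagonist gene Hhip had 0%. The Wnt list had 10 of 25 members marked (40% against 27.5% expected, adjusted permutation p = 0.231), with Dvl3 at 72.4%, Dvl2 at 66.3% (overlapping Acadvl) and the receptor gene Lrp5 at 59.3%, and with the ligand gene Wnt3 and the antagonist gene Dkk1 at 0%. For the BMP and TGF-beta list the count was 9 of 24 (37.5% against 25.4% expected, adjusted permutation p = 0.253; 16.7% in replicate 1 and 29.2% in replicate 2), with the ligand gene Tgfb3 at 52.0% (its body overlaps Ttll5), Smad5 at 46.0% and Smad7 at 34.3%, and with the receptor gene Bmpr1b and the antagonist gene Grem1 at 0%. The FGF list had 3 of 20, against 29.5% expected (adjusted permutation p = 0.231). These were Fgfr1 (36.6%), Spry1 (36.1%) and Fgfr3 (25.9%), while Fgf10 and Fgf15 had 0%. In the replicates' own lists Fgfr3 was under the threshold, with 9.98% in replicate 1 and 16.9% in replicate 2. The share of FGF members marked was 10% in each. Fgfr2, also in this list, was unmarked at 7.34%, but its annotated body of 2960900 bp spans many other genes. Orofacial cleft genes were marked in 11 of 35 cases, 31.4% against 28.1% expected (adjusted permutation p = 0.768). The best covered were the ribosome biogenesis gene Tcof1 (82.2%), which is mutated in Treacher Collins syndrome, the spliceosome gene Eftud2 (78.7%) and Polr1c (59.6%), a subunit of RNA polymerases I and III, while Cdh1 and Fgf8 had 0%. Marked against unmarked is a threshold on covered length: at 10% cover the Wnt and BMP lists also passed the test, and at 40% the hedgehog list, with 4 of 14 marked, no longer did (adjusted permutation p = 0.335). In the list of replicate 1 and at 40% cover the BMP difference changed direction.

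Few genes in the lists of other cell types of the head were marked. The facial mesenchyme transcription factors were also seldom marked (7.5%), so few marked genes do not show that a cell type was absent. Expression was not measured here. None of the genes of skeletal muscle (17 tested), neurons (17), erythroid cells (17), endothelium (14), forebrain and eye (15) or glia and migratory neural crest (11) was marked, with adjusted permutation p from 0.0136 to 0.042. The best covered member of its list was Erbb3 for glia (10.9%), Alas2 for erythroid cells (4.75%, overlapping Apex2), Egfl7 for endothelium (3.94%, overlapping Agpat2) and the titin gene Ttn for muscle (0.960%). In surface ectoderm and epithelium 1 of 21 genes was marked, Esrp2 (37.9%), whose body overlaps Nfatc3 (adjusted permutation p = 0.0219), and in cartilage and bone 1 of 19, the cartilage collagen gene Col2a1 (68.4%, 60.7% ± 6.11 in the replicates' own lists, SD, n = 2; adjusted permutation p = 0.0331). Sox9, the master regulator of cartilage, had 11.1% and Acan 0%. Of 14 macrophage genes only Cd68 was marked (adjusted permutation p = 0.253), with 100% of its 1941 bp under a domain on chromosome 11 (69663653 to 69671035) that also runs over the translation factor gene Eif4a1. In addition, the genes of hepatocytes (16 tested), testis germ line (15), lymphocytes (12), late epidermis (12), pancreas (12) and photoreceptors (11), which served as lists of other organs, had no marked member (adjusted permutation p from 0.0106 to 0.036), and neither did the cardiomyocyte list (11 tested, adjusted permutation p = 0.0753). Several of these short lists pass the threshold narrowly, and leaving out genes that overlap others or raising the threshold to 40% cover ends most of these calls. The lists of cartilage and bone, glia and photoreceptors pass in neither replicate's own list, and those of surface ectoderm, endothelium, late epidermis and pancreas not in that of replicate 1.

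Multigene families stood at both ends. No member of the Hox clusters (39 genes), the olfactory receptors (1134), the vomeronasal receptors (330) or the defensins (64) was marked (adjusted permutation p = 0.0008 for each), nor were the replication-dependent histones (67 genes, adjusted permutation p = 0.00262, a call that ends among genes of at least 5 kb, where 3 members are left) or the keratin-associated genes (57 genes, adjusted permutation p = 0.00926, a call that ends at 40% cover, among genes that overlap no other and among genes of at least 5 kb). The Zfp family, which encodes zinc finger proteins, was marked in 226 of 394 cases, 57.4% against 35.9% expected (adjusted permutation p = 0.0008). It was led by Zfp869 (91.1%), Zfp606 (87.4%) and Zfp335 (87.2%, overlapping Pcif1). Replicated peaks covered 0% of Zfp114 and Zfp174, though Zfp174 had 5.23% in replicate 1 and 2.17% in replicate 2. The 5 peaks of highest enrichment all lay at Zfp genes. The first, with an enrichment of 14.97, spanned Zfp784 and Zfp865 with their neighbour Ccdc106 on chromosome 7 (5027417 to 5036654), 83.0% of it exonic. It was followed by Zfp37 on chromosome 4 (62191126 to 62196144, enrichment 13.0), Zfp354c on chromosome 11 (50811881 to 50818637, enrichment 12.7), Zfp763 on chromosome 17 (33017649 to 33020350, enrichment 12.6) and Zfp27 on chromosome 7 (29891670 to 29897334, enrichment 12.5). Of the clustered protocadherins, which encode cell adhesion proteins, 21 of 56 were marked (adjusted permutation p = 0.0042). These were all 21 members of the gamma cluster, such as Pcdhga4 with 43.0% covered, and none of the 13 alpha or 22 beta members. The gamma genes overlap one another, so that the same peaks count for many of them, and the random lists do not allow for this; the call also ends at 10% cover (adjusted permutation p = 0.0994) and without length matching (adjusted Fisher's exact p = 0.263). Imprinted protein-coding genes were marked in 10 of 20 cases (adjusted permutation p = 0.0437), among them the receptor gene Igf2r (59.0%) and also Mcts2 (100%) and Nnat (83.4%), which lie inside H13 and Blcap. Cdkn1c and Dlk1 had 0%, and the share marked was 35% in replicate 1 and 50% in replicate 2. This call ends without members that overlap other genes (6 of 15 marked, adjusted permutation p = 0.361), in the list of replicate 1 (0.303), in the pooled list (0.101), at 10% (0.183) and 40% cover (0.205), among genes of at least 5 kb (0.101), by medians (0.141) and without length matching (adjusted Fisher's exact p = 0.0638).

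**Figure D3:**
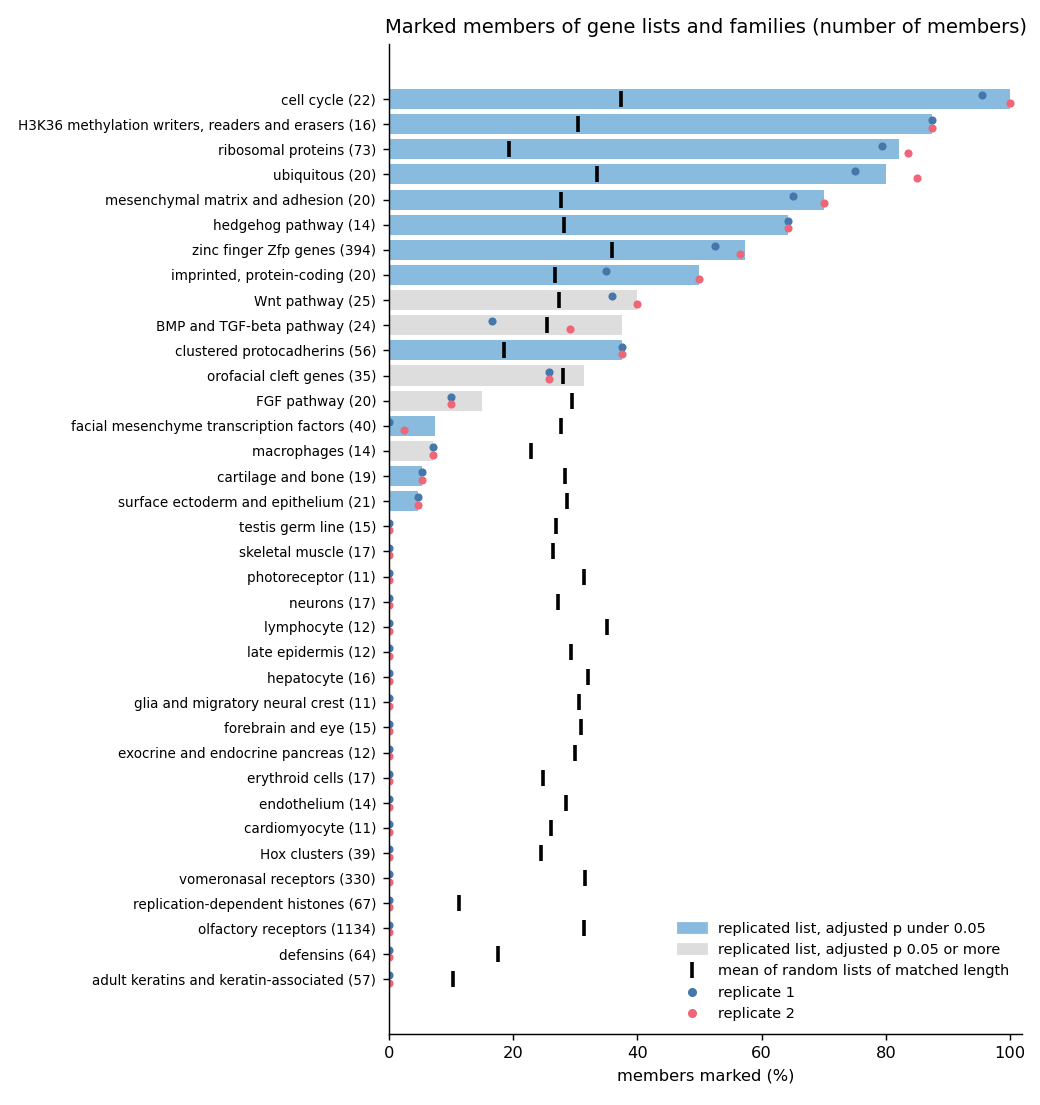
Share of members marked (%, x axis) for the 36 gene lists and families, with the number of members in brackets. Bars give the replicated list, in blue where the adjusted p was under 0.05, black ticks the mean of 10000 random lists of matched gene length, and points replicate 1 (blue) and replicate 2 (red). The cell cycle list is at 100% and 19 lists are at 0%.

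The last question was how chromosome X compared with the autosomes. Few genes on X were marked: 51 of 948, or 5.38%, against a median of 31.3% over the 19 autosomes. Those covered most were Asmt (72.9%), the filamin gene Flna (69.4%), Maged1 (64.0%), the transcriptional co-regulator gene Hcfc1 (58.1%) and Armcx4 (52.8%), the 5 highest shares, named after their values were seen. The ubiquitous, cell cycle, H3K36 methylation and ribosomal lists have 6 members on X: Pgk1 (25.6%), which was marked, Rps4x (10.98%), Rpl39 (10.6%), Hprt (1.48%), and Rpl10 and Rpl36a with 0%. In the replicates' own lists the share on X was 3.53% ± 0.671 (SD, n = 2). The autosomes ran from 22.3% on chromosome 14 to 39.2% on chromosome 8, and none was below X. With 1 chromosome set against 19 the smallest two-sided p of an exact permutation test over chromosomes is 0.1, so this test cannot pass the threshold. Replicated peaks on X covered 0.362% of the chromosome, with 973 peaks and a median enrichment of 2.92.

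**Figure D4:**
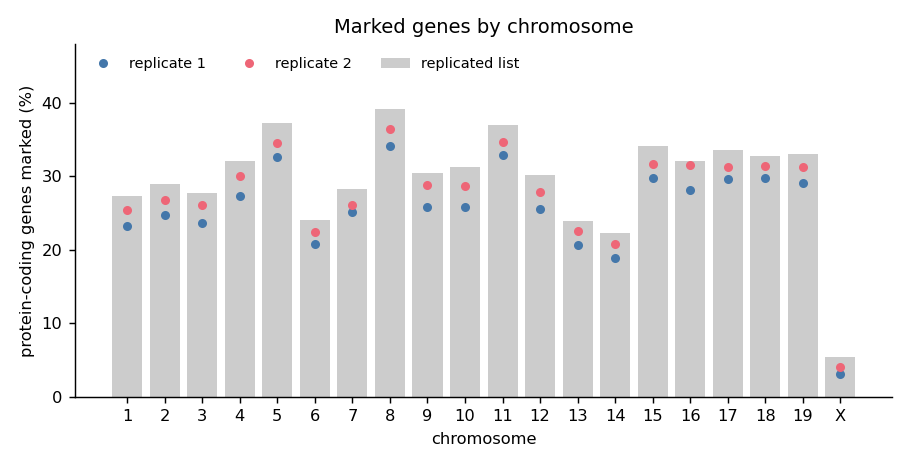
Share of protein-coding genes marked (%, y axis) on each chromosome (x axis), for the replicated list (grey bars) and the lists of replicate 1 (blue points) and replicate 2 (red points). Chromosome X stands at 5.38%, below all 19 autosomes, which run from 22.3% to 39.2%.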

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

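The tests of gene length and gene content on chromosome X, and of Zfp genes with a neighbour, were chosen only after the result was seen. Peaks also stood in parts of the data that no comparison uses: 5 replicated peaks on chromosome Y and 6 on unplaced or unlocalized sequence, more than the limit set for a count of 0. For Y this limit tests nothing, since both pools held embryos of both sexes and a count of 0 was never the expected value. For the other sequence, too, nothing in the data made 0 the expected count. Of those on Y, 1 lay at Ddx3y (1278386 to 1278719, enrichment 2.82), a gene of the male-specific region, and the other 4 lay between 90738658 and 90745851, where no gene is annotated. Outside Y the highest enrichment was 7.55, on sequence unlocalized on chromosome 4, and the peak on unplaced sequence had 1.53. The origin of these peaks was not tested.

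Genes on chromosome X were seldom marked, 5.38% of them. Gene length does not account for this, since length-matched autosomal genes were marked in 27.6% of cases on average (23.5% to 32.7% over 1000 draws). Gene content was tested only in broadly used genes. On X 1 of 6 members of the ubiquitous, cell cycle, H3K36 methylation and ribosomal lists was marked (Pgk1). On autosomes 111 of 125 were (Fisher's exact p = 0.000213). For such genes the share on X was thus lower, but 6 members cannot rule out gene content for the other X genes. Fewer reads from X, which males hold in 1 copy, stay open as a part. At matched −log10 p and width the median enrichment of X peaks was 3.00, above every autosome (2.92 to 2.94). Fewer reads behind each peak would give this, but the ratio to the autosome median was only 1.02. Without matching, the X median was lower, 2.92 against 3.25 for autosomal peaks. Read numbers are unknown, so how large this part is cannot be told. No biological explanation was tested.

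Peaks at Zfp genes made up 12.9% of the 1000 peaks of highest enrichment and 2.10% of all peaks. GC content does not account for this, with at most 3.40% in GC-matched draws, nor do peak width and exon content, with at most 5.40% in draws matched on both. At isolated Zfp genes, with no other such gene within 500 kb, the share was 2.90%, above the highest of the matched draws (2.40%). Reads or copies shared with a Zfp gene that near thus do not account for all of it. Zinc finger genes under other symbols and paralogs farther away were not counted as neighbours, so sharing with those was not tested. Sharing with near Zfp genes may add to it. Of the peaks at Zfp genes with a neighbour 8.61% were among the 1000, against 2.55% at isolated ones (Fisher's exact p = 1.5e-10). No biological explanation was tested.

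Facial mesenchyme transcription factors were seldom marked, 3 of 40. GC content does not account for this: random lists of matched GC content were marked in 32.4% of cases (permutation p = 0.0004). Peaks too short for the 20% threshold stay open. Of the members 45%, such as Pbx1, Msx1 and Six1, had at least 1 base under a replicated peak, against 44.0% in random lists (permutation p = 1). Any covered base was enough for this count. At Pbx1 the covered length was not short, at 10.3% of a body of 312907 bp. The list thus may differ in how much of each gene is covered and not in how many genes have any covered base. No biological explanation was tested.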

How the results depend on the processing

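All alternatives were chosen before the result was seen. Of 447 values recomputed under them, 339 counted as the same. The −log10 q filter kept 99.3% of the replicated peaks and the −log10 p filter 103474 of 109603. The 41 values counted as the same under each of these filters thus say little. At 40% cover 20 counted as the same, and with medians 12. Tested values had to stay on the same side of the threshold with no change of direction, and counts of genes within 1.5 times the main count. Overlaps of peaks had to stay within the binomial interval of the main share, and correlations across genes always counted as moved. Other values without a test had to move by less than the spread between replicates. Among the values that differed, 82 no longer passed the threshold without changing direction (18 of them at a difference of 0, which has no direction). A further 4 passed it newly, 4 changed direction and 18 moved. The ubiquitous, H3K36 methylation, cell cycle, matrix, Zfp and ribosomal lists were marked more often under every alternative, and the macrophage list never passed the threshold. The share of peak length in gene bodies stayed 52.8 to 53.9 percentage points above shuffled peaks, the 3' part of marked genes 36.2 to 46.4 points above the 5' part, and internal exons 13.5 to 14.9 points above their flanks. The values for lists below are the share of members marked minus that of random lists, in percentage points. Except where said, the cause was not tested.

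With the pooled peaks, the threshold was no longer passed by cartilage and bone (-21.8) and the imprinted genes (19.2), and was newly passed by cardiomyocyte genes (-29.6). With each replicate's own list, the values ran from -4.17 to 5.99 for BMP and TGF-beta and from -0.174 to 2.08 for orofacial cleft genes, which changed direction. They ran from -22.3 to -20.2 for surface ectoderm, -20.9 to -18.9 for cartilage and bone, -26.3 to -24.3 for endothelium, -28.7 to -26.8 for glia, 12.3 to 25.4 for imprinted genes, -27.6 to -26.1 for late epidermis, -29.1 to -27.3 for photoreceptors and -27.9 to -26.1 for pancreas, each past the threshold in 1 replicate or in none.

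With genes called marked at 10% cover, the threshold was newly passed by Wnt (28.7), BMP and TGF-beta (24.2) and cardiomyocyte genes (-31.7), and no longer by cartilage and bone (-19.9), glia (-28.9), imprinted genes (16.4) and protocadherins (11.05). At 40% cover BMP and TGF-beta changed direction (-4.99). The lists no longer past the threshold there were hedgehog (13.2), surface ectoderm (-18.2), skeletal muscle (-17.2), cartilage and bone (-11.8), endothelium (-17.0), erythroid cells (-15.9), neurons (-16.2), glia (-19.2), forebrain and eye (-20.1), imprinted genes (14.1), hepatocytes (-21.2), testis (-17.3), late epidermis (-19.7), lymphocytes (-24.0), photoreceptors (-19.6), pancreas (-19.5) and keratin-associated genes (-6.48).

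Among genes that overlap no other, which leaves fewer genes per list, these were skeletal muscle (-23.2), cartilage and bone (-19.8), endothelium (-22.5), erythroid cells (-20.9), neurons (-21.6), glia (-27.6), forebrain and eye (-28.7), imprinted genes (14.2), testis (-23.9), late epidermis (-24.6), lymphocytes (-31.6), photoreceptors (-28.8), pancreas (-26.1) and keratin-associated genes (-6.57). No protocadherin is free of overlap, so this family has no value there. Among genes of at least 5 kb they were surface ectoderm (-25.1), glia (-34.2), imprinted genes (24.8), late epidermis (-33.9), pancreas (-35.1), histones (-32.9) and keratin-associated genes (-31.3). With Fisher's exact test without length matching they were glia (-29.7), imprinted genes (20.3), photoreceptors (-29.7) and protocadherins (7.80).

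With the median covered share in place of the count of marked members, most lists marked less often could not differ, because 52.4% of all genes have no covered base and the medians of random lists were near 0. The difference was 0 for facial transcription factors, surface ectoderm, skeletal muscle, erythroid cells, neurons, glia, forebrain and eye, Hox clusters, hepatocytes, testis, late epidermis, pancreas, olfactory and vomeronasal receptors, protocadherins, histones, defensins and keratin-associated genes. It was -0.306 for cartilage and bone, -1.06 for endothelium, -0.846 for lymphocytes, -0.346 for photoreceptors and 15.4 for imprinted genes, none past the threshold, and the FGF list changed direction (3.28).

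The overlap of replicate 1 peaks by replicate 2, and the reverse, were 60.1% and 54.1% when 50% of the peak had to overlap, 28.9% and 35.8% with a reciprocal 50%, 70.8% and 66.8% at −log10 q of at least 2, 71.3% and 62.6% at −log10 p of at least 5, and 74.7% and 64.3% with the same number of peaks. The correlation across genes was 0.971 at −log10 q of at least 2 and 0.985 for genes of at least 5 kb. The count of marked genes, 6457 in the main setting, was 7871 at 10% cover, 4020 at 40% cover, 7276 in the pooled list, 4488 among genes that overlap no other and 5579 to 6023 in the replicates' own lists. Chromosome X stood below the autosomal median by -28.0 percentage points in the pooled list, -30.1 at 10% cover, -17.5 at 40% cover and -21.5 among genes that overlap no other, and by -24.8 to -22.7 in the replicates' own lists. The depth is unknown, so what it limits cannot be given.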

Other observations

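Long non-coding RNA genes were in no comparison, and those named here were chosen after their values were seen. The maternally expressed genes of the imprinted Dlk1 locus on chromosome 12 carried the mark: Meg3 was covered over 49.5% of its body (35.2% ± 1.71 in the replicates' own lists, SD, n = 2), Rian over 26.0% (21.5% ± 5.61) and Mirg over 56.6% (44.6% ± 11.8). The host gene of the miR-17 cluster, Mir17hg, which acts in cell growth, had 75.6% (62.0% ± 10.2). Among hosts of small nucleolar RNAs, Snhg1 had 66.8% and Gas5 56.2%, while Snhg14 had 0.06%. On chromosome 19, Malat1 had 52.7% (40.2% ± 1.79) and its neighbour Neat1 had 0%. Hotair and Hottip, which lie in Hox clusters, had 0%, and H19 had 14.8%, with 0% in replicate 1 and 8.72% in replicate 2. Of 5485 genes annotated as long non-coding RNA genes and lying outside protein-coding genes, 69 (1.26%) were marked. No test was made of this share, and the annotated class of each gene was not checked.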
